A study of Rattus norvegicus with 6 samples.

How the data were processed

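RNA was sequenced in bulk from cultured rat spinal cord ependymal stem cells, which are cells that line the central canal of the spinal cord and can act as neural stem and progenitor cells. The labels place 3 libraries in a control group kept in neurobasal medium and 3 libraries in a group that also received 500 uM glutamate, all taken at day 2. Libraries were prepared with a directional (strand-marking) kit, per the labels' protocols. The labels number the libraries 1 to 3 in each group but do not say whether they came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

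The authors deposited 1 table of raw read counts per library, with a count for each Ensembl gene ID, per the file headers. Each table held 32883 gene rows, and 10944 of these had no count in any of the 6 libraries. The submitters' processing notes name the rat genome build rn6 and the tools Trim Galore 0.6.5, STAR 2.7.8a, SAMtools and featureCounts 2.0.1. The annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. Genes that share reads with a near-identical copy, or that overlap a gene on the other strand, are therefore uncertain.

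The files do not pair the gene IDs with gene names. In the RefSeq gene table used here (assembly GRCr8), 0 rows carry an Ensembl ID, so none of the 32883 IDs could be looked up in it. The gene lists fixed before the data were examined (cell cycle, glutamate receptors and transport, cell type markers of glia, neurons, ependyma and other tissue, stress, sterol, matrix, inflammatory and developmental pathways), the mitochondrial and ribosomal protein shares and the genes chosen by symbol could not be evaluated. Genes are described here by groups of abundance and size of change, and at most 2 IDs per direction are printed. These are the IDs with the largest fitted change among genes that passed adjusted p below 0.05, had a mean CPM of at least 5 and had no overlap between the 3 glutamate and the 3 control values. This is the rule set beforehand, with its requirement of a gene name dropped and the number per direction lowered. Without the name requirement 1447 rises and 1803 falls met it.

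Total counts ran from 166567977 to 181352365 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 15919 genes. Libraries were scaled by TMM, dispersions and quasi-likelihood fits were robust, and glutamate was tested against control with glmQLFTest over all 6 libraries without further covariates. P-values were adjusted by the Benjamini-Hochberg method and genes were called at adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values were computed from the deposited counts with TMM-scaled library sizes. Genes were also divided by mean CPM over the 6 libraries into classes bounded at 1, 10 and 100, a division chosen after the files were opened, as were the bars used for genes near absence in 1 group. Principal components were computed on log2 CPM with a prior count of 2. Totals, detected genes and the share of the 10 most abundant genes were compared between groups with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

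Duplicate libraries were looked for with a chi-square statistic over genes with at least 10 counts in a pair. It ran from 19.0 to 160.3 per gene within groups, where sampling noise alone gives 1, so all 6 libraries were treated as separate samples. The fit was tested on simulated data drawn from the real mean per gene and the real library sizes, with dispersions taken from their trend with abundance. In it 15767 genes were tested and 200 were changed. It recovered 40% of genes changed by 1.3-fold, 68% of those changed by 1.5-fold, 96% of those changed by 2-fold and 100% of those changed by 4-fold, with 50 genes at each size. Of its calls, 6.75% were unchanged genes, and a simulation with no changed gene gave 0 calls. The simulation leaves out the spread of single genes around the trend. It also changed far fewer genes than the 4413 called in the data, so these rates may not carry over to the data.

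Alternatives fixed before the data were examined were scaling by RLE factors or by total counts, DESeq2 1.42.0, no low-count filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. A test against a fold change of 1.5 (glmTreat), bars of 10 counts, 100 counts and 1 CPM for a detected gene, thinning of every library to the smallest total, and the counts of rises and falls per abundance class under each setting were added after the data were seen. The labels give no batch, date or litter.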

Results

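Gene expression was measured by bulk RNA sequencing in rat spinal cord ependymal stem cells cultured with or without glutamate, to ask how their transcriptome responds to a level of this neurotransmitter that is toxic to neurons. There were 3 control libraries and 3 libraries from cells given 500 uM glutamate, all at day 2. Control libraries held 176531121 ± 6824832 counts (SD, n = 3) and glutamate libraries 172428717 ± 5598461 (SD, n = 3), a difference smaller than the spread between libraries (exact two-sided permutation p = 0.5). At this depth 1 CPM corresponds to well over 100 reads, and the estimated variance between replicates exceeded the counting variance in 95.3% of genes tested. The common biological coefficient of variation was 0.105.

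The treatment separated the libraries on the first principal component of log2 CPM, which carried 63.0% of the variance. All 3 control libraries had scores from -43.5 to -29.8 and the 3 glutamate libraries from 32.0 to 37.7. The second component carried 14.9% and spread the control libraries, from 29.8 for control replicate 1 to -26.9 for control replicate 3. The glutamate libraries lay between -5.4 and 8.4 on it.

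**Figure D1:**
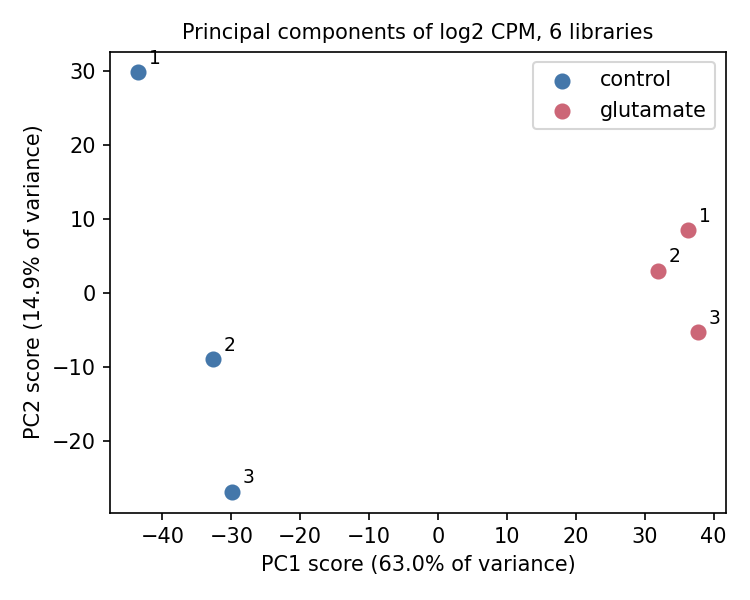
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with each point a library, coloured by group and marked with its replicate number. The groups separate on the first component, which carries 63.0% of the variance, and control replicate 1 lies apart from the other control libraries on the second.

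Glutamate changed the expression of 4413 of 15919 genes tested, or 27.7% (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 2239 rose and 2174 fell, a share of rises of 50.7%. Most changes were small: 2932 of the called genes, or 66.4%, differed by less than 1.5-fold. The rises had a larger median change than the falls, 1.48-fold (quartiles 1.27 and 2.06) against 1.26-fold (quartiles 1.20 and 1.40) for the falls. This gap narrowed with abundance. It was 2.59-fold against 2.15-fold below a mean of 1 CPM, and 1.24-fold against 1.21-fold at 100 CPM or more. The median log2 fold change over all tested genes was -0.01. The glutamate and control libraries did not overlap in 7454 tested genes, or 46.8%, where 10% is the share chance gives for 3 against 3. Without control replicate 2 the count of calls was 2603, and it was 2442, 2420 and 2436 without glutamate replicates 1, 2 and 3. The share of rises was then 59.1%, 60.2%, 61.0% and 57.3%, so the even split did not hold under these. Tested against a change of 1.5-fold in place of no change, 430 genes rose and 104 fell.

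Among changes of 2-fold or more, rises outnumbered falls. Such changes were found in 740 genes, of which 597 rose and 143 fell, so that 80.7% were rises. At 4-fold or more, 205 genes rose and 10 fell, and at 8-fold or more 88 rose and 1 fell. With a filter of 1 CPM in 3 libraries, 332 genes rose and 59 fell by 2-fold or more.

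The calls were divided by the abundance of the gene. Among the 3848 tested genes with a mean below 1 CPM, 419 rose and 142 fell, and 312 rises and 82 falls reached 2-fold. With 1 library left out this class gave 237 to 429 rises and 64 to 148 falls, with rises ahead in each fit. Of the 2993 genes between 1 and 10 CPM, 566 rose and 401 fell, with 179 rises and 43 falls of 2-fold or more. Rises also led here in each fit with 1 library left out, with 391 to 659 rises and 212 to 443 falls. The 6678 genes between 10 and 100 CPM gave 1229 falls and 853 rises, of which 18 falls and 90 rises reached 2-fold. The larger number of falls in this class did not hold in every fit with 1 library left out, and the cause was not tested. There were 556 falls and 593 rises without control replicate 2, and 506 and 564 without glutamate replicate 1. Without glutamate replicates 2 and 3 there were 495 falls and 563 rises, and 546 and 531. Falls led more clearly without control replicate 1 (1529 against 1092) and without control replicate 3 (1520 against 1287). Genes at 100 CPM or more were called 401 times as rises and 402 times as falls, and the 16 that changed by 2-fold or more all rose. With 1 library left out, rises made up 47.9% (without control replicate 3) to 59.0% (without glutamate replicate 1) of the calls in this class. The latter fit gave 239 rises and 166 falls. The exact 95% confidence interval for the percentage of rises among 2-fold changes ran from 74.8 to 83.1 in the class below 1 CPM and from 74.9 to 89.8 in the class from 10 to 100 CPM, treating genes as independent, which they are not.

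**Figure D2:**
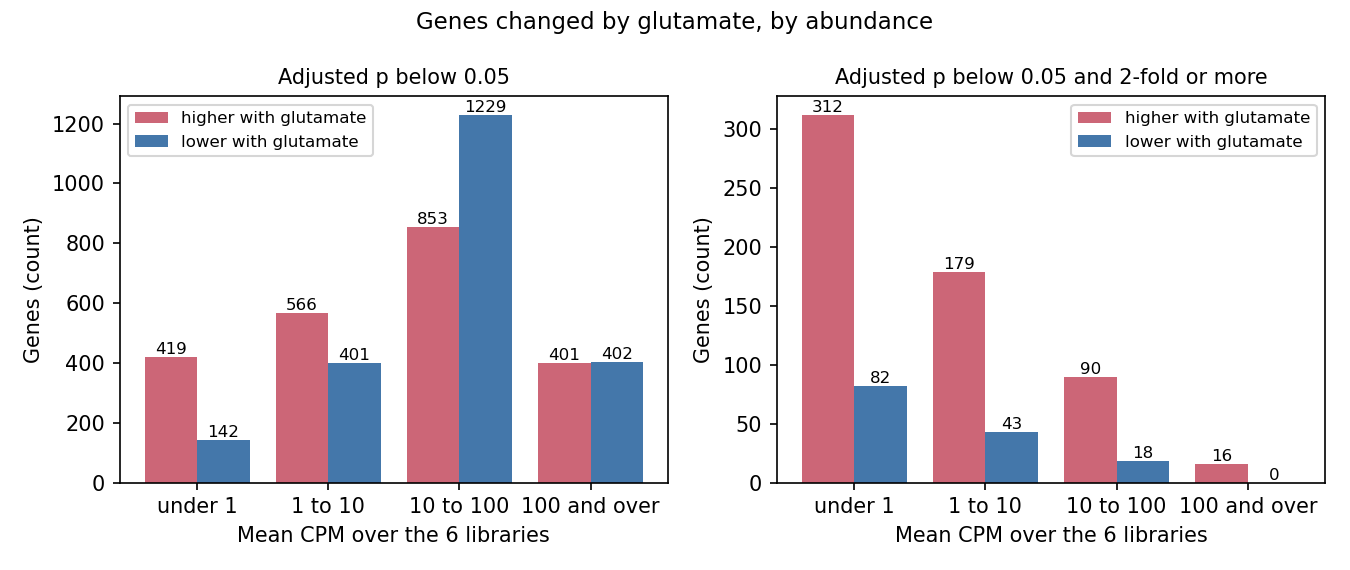
Number of genes (y axis) that were higher or lower with glutamate in each class of mean CPM (x axis), for all genes past adjusted p 0.05 (left) and for those that also changed by 2-fold or more (right). Rises exceed falls among 2-fold changes in all 4 classes, while all calls between 10 and 100 CPM hold 1229 falls and 853 rises, an order that turned without control replicate 2, glutamate replicate 1 or glutamate replicate 2.

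The largest rise among genes with a mean of at least 5 CPM was that of ENSRNOG00000015055, from 0.461 ± 0.044 CPM in control libraries to 27.0 ± 1.6 CPM with glutamate (SD, n = 3 each). Its log2 fold change was 5.87 (SE 0.11, edgeR adjusted p = 9.55e-09), a 58.4-fold rise that rests on at least 74 reads in each library. ENSRNOG00000058645 followed, with 3.11 ± 0.36 CPM in control libraries and 126.4 ± 23.0 CPM with glutamate (SD, n = 3 each). Its log2 fold change was 5.34 (SE 0.16, edgeR adjusted p = 8.17e-07), or 40.6-fold. The largest falls were smaller. ENSRNOG00000001628 went from 13.2 ± 2.6 to 3.26 ± 0.37 CPM (SD, n = 3 each), a log2 fold change of -2.02 (SE 0.15, edgeR adjusted p = 1.89e-05). ENSRNOG00000021201 went from 47.8 ± 9.3 to 12.03 ± 3.11 CPM (SD, n = 3 each), a log2 fold change of -1.99 (SE 0.23, edgeR adjusted p = 0.00169). These falls were 4.05-fold and 3.97-fold. The files do not pair these IDs with names or positions.

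**Figure D3:**
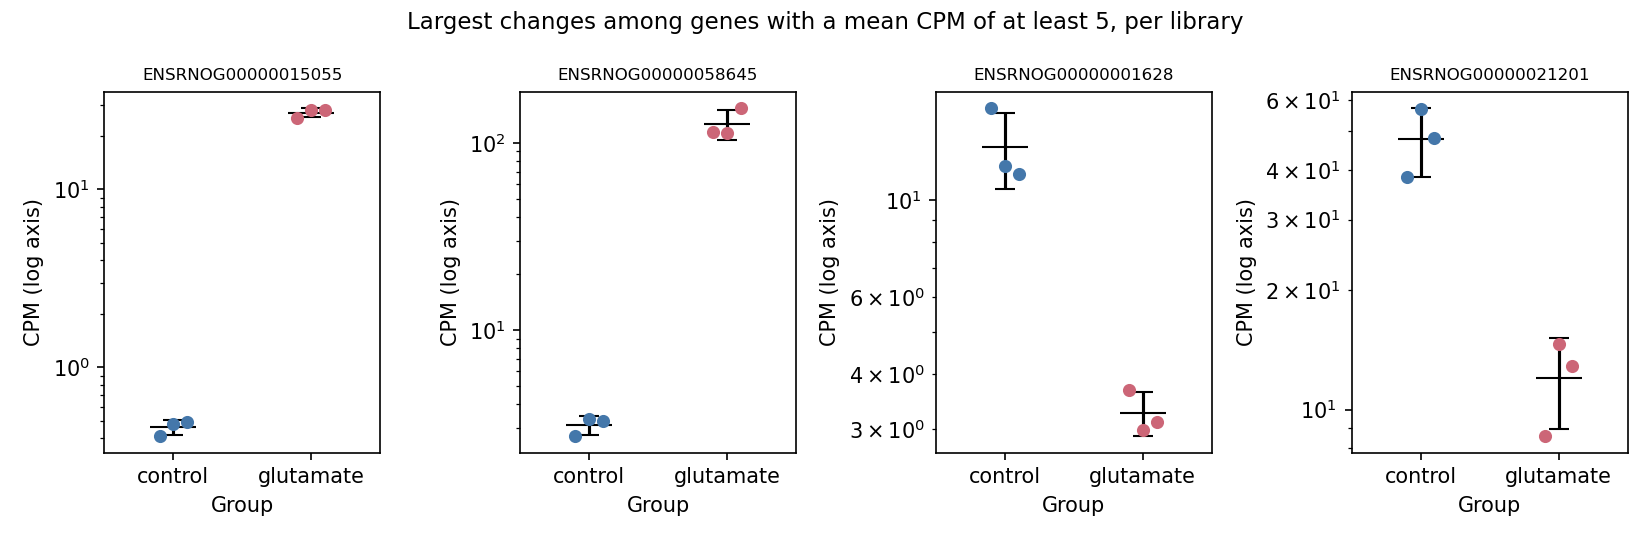
CPM (y axis, log scale) of the pair of genes with the largest rise and the pair with the largest fall, among called genes with a mean of at least 5 CPM, in the control and glutamate groups (x axis). Points are single libraries and black marks the group mean ± SD (n = 3); the groups do not overlap for any of the 4 genes, and ENSRNOG00000015055 goes from 0.461 to 27.0 CPM.

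A small set of genes went from near absence to clear expression. In 6 genes every control library was below 0.1 CPM and every glutamate library at 1 CPM or more, and all 6 were called as rises. In the opposite direction 0 genes met the same bars. With no count in 1 group and at least 10 counts in every library of the other as the bars, 6 genes were present with glutamate alone and 1 in control libraries alone. Glutamate libraries also detected more genes, with 19344 ± 77 genes having at least 1 count against 19027 ± 84 in control libraries (SD, n = 3 each). The difference of 317 genes was 173 at a bar of 10 counts, 118 at 100 counts and 133 at 1 CPM. At 1 count every glutamate library exceeded every control library, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries allow (0.15 after Benjamini-Hochberg adjustment over 3 library measures).

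The most abundant transcripts changed little. Of the 100 most abundant genes, which took 17.2% to 18.6% of the counts of a library, 14 rose, 18 fell and 68 were not called. None of these 100 genes changed by 2-fold, with a largest rise of 1.55-fold and a largest fall of 1.53-fold. The 10 most abundant genes took 5.27% ± 0.14 of control counts and 5.05% ± 0.04 of glutamate counts (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.15). The genes that rose accounted for 13.3% ± 0.5 of counts in control libraries and 17.8% ± 0.2 with glutamate, and those that fell for 19.4% ± 0.8 and 15.4% ± 0.1 (SD, n = 3 each). Those that rose by 2-fold or more went from 0.393% ± 0.016 to 1.17% ± 0.05 of counts (SD, n = 3 each). These shares describe genes selected by the test and are not a separate test of it.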

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

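The count of called genes kept within 1.5 times of its value (4413) under RLE factors, total counts and DESeq2. It also did so with no low-count filter, a filter of 1 CPM in 3 libraries and the replicate block. No called gene that was still tested changed sign under these or when a library was left out. In 99.8% of called genes the groups did not overlap, so leaving out a library could hardly change a sign. The share of calls that rose stayed within 10 percentage points of 50.7% under both other scalings, which moved the median log2 fold change by under 0.1, but ran from 50.4% to 61.0% when 1 library was left out and was 80.5% in the test against 1.5-fold. Between 10 and 100 CPM, falls less rises were 376, from -68 to 437 when 1 library was left out, and -80 against 1.5-fold; the cause was not tested. Leaving out 1 library gave 2420 to 5584 called genes (1397 to 2921 rises, 945 to 2663 falls), and 196 to 2023 of the original calls were lost. The test against 1.5-fold, added after the data were seen, called 534 genes (430 rises, 104 falls), of which 455 (383 rises, 72 falls) changed by 2-fold or more. The CPM filter left 391 genes changed by 2-fold or more (332 rises, 59 falls), because it tests 12140 genes and leaves out those of low abundance. The 4 printed IDs kept their direction and their call in all 52 combinations of ID and alternative (largest adjusted p 0.0105). These IDs were chosen from the same data as the largest changes without overlap, so this does not bear on the other calls. The replicate block called 4553 genes, 4108 of them shared with the unblocked fit. Whether the numbers pair the libraries is not stated in the labels and stays open. The correlation of same-numbered deviations was 0.101, -0.024 and 0.135, over 0.1 in 2 of 3 pairs. In each group 2 of 3 libraries correlated best with their own number. Under the block the SE of ENSRNOG00000021201 was 0.078, against 0.234 without it, and the SEs of the other printed IDs were also smaller. The planned tests of gene lists were not run under any alternative, because the IDs carry no names. Depth limits few genes, since replicate variance exceeded counting variance in 95.3% of those tested. On simulated data with 200 changed genes the fit recovered 40% of 1.3-fold changes, a rate that may differ in the real data. A gene without a call is therefore not shown to be unchanged.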

Other observations

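The tests of genes with few reads, of other cell types and of the bar of 1 CPM, and the reading of the scalings as a test, were chosen after the results they bear on had been seen, as were the counts of other splits. The scalings themselves were planned. The thinning test and the bar of 100 counts were set before their results were seen.

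Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 4413 called genes, and the same held for the 740 genes called with changes of 2-fold or more. The highest other split gave 0 for both. Every other split mixes control and glutamate libraries, so the difference between groups widens its spread and makes calls unlikely. The 0 is thus no measure of chance, and 10 splits are too few for a share under 0.05.

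Most of the excess of large rises over large falls (597 against 143) lay in weakly expressed genes, with 441 rises and 114 falls at a mean below 5 CPM (79.5% rises, exact lower 95% bound 75.9%). With a mean of at least 5 CPM there were 156 rises and 29 falls of 2-fold or more, 84.3% rises, with an exact lower 95% bound of 78.3%. Noise of genes with few reads, which gives rises and falls alike, is thus argued against as the whole cause in both ranges. The bounds treat genes as independent, which they are not. The range below 5 CPM also holds genes with many reads at this depth, so it is not a test of genes with few reads alone. The scaling between libraries stays open: the lowest percentage of rises under RLE factors or total counts was 80.9%, but these moved the median log2 fold change by under 0.1 and so could not test it. RNA from another cell type in the glutamate libraries, or a change in the mix of cells, may contribute and stays open, because the reference table used here holds an Ensembl ID in 0 rows and no marker gene could be looked up. A response of the ependymal cells to glutamate, the difference the design names, is likewise open and was not tested apart from these.

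Glutamate libraries detected 317 more genes on average than control libraries. Deeper glutamate libraries are argued against by the totals, which averaged 172428717 counts with glutamate and 176531121 in control. With every library thinned to the smallest total, the lowest glutamate library still detected 171 more genes than the highest control library, against a larger group SD of 79. A diffuse background of a few reads per gene is argued against for genes at 1 CPM or more, where the lowest glutamate library exceeded the highest control library by 101 genes, against an SD of 20. That excess need not be a part of the 317, because a gene can cross 1 CPM while already detected in control libraries. For the difference of 317 genes at 1 count such a background stays open. At a bar of 100 counts the lowest glutamate library fell short of the highest control library (a gap of -1 genes), although the group means differed by 118 genes. The outcome set beforehand for such a background, no excess of the lowest glutamate library over the highest control library, was thus met. That bar lies below 1 CPM at this depth and is not scaled to depth, while control libraries held more counts on average. With group means that still differed, it does not decide the question, and the background stays open. A candidate explanation is that glutamate turns on genes that control cells keep nearly silent. Only 6 genes went from below 0.1 CPM in every control library to 1 CPM or more in every glutamate library. These genes can hold some reads in control libraries, so they need not add to the difference of 317. With no count in any control library and at least 10 counts in every glutamate library there were also 6 genes. Consistent switching at either bar can thus cover few of the 317, while weaker switching stays open and untested.

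Control replicate 1 stood farther from the other libraries of its group than any other library did from its own. The chi-square statistic per gene was 88.3 and 160.3 between control replicate 1 and control replicates 2 and 3, 32.0 between control replicates 2 and 3, and 19.0 to 45.4 among glutamate libraries. The lowest value between groups, 151.7 for control replicate 3 and glutamate replicate 2, was below the 160.3 between control replicates 1 and 3. The count of called genes was 5311 without control replicate 1, 2603 without control replicate 2 and 5584 without control replicate 3, so a higher count was not particular to leaving out the first.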
